A study of Mus musculus with 8 samples.

How the data were processed

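Whole embryos of 4 genotypes were the starting material: wild type (WT), a paternal (PKI) or maternal (MKI) knock-in of polyadenylation cassettes at Gtl2, and both (HOMO). Per the labels' protocols, total RNA was selected with oligo(dT) beads, second strands were marked with dUTP, and libraries were read as paired ends on a NovaSeq instrument. How the small-RNA libraries were made is not given in the sources used here. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d were used on GRCm38; DESeq2 and edgeR are named there without version or role. The annotation release, and whether a column is a single library or a combination of libraries, are not given in the sources used here. Oligo(dT) selection favours RNAs with a poly(A) tail, so levels of RNAs without a tail, such as most histone transcripts, depend on how complete that step was.

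The deposited mRNA and long non-coding RNA values were taken as FPKM made by the authors, because StringTie is the quantifier the notes name and the values are not whole and have different column sums; the table headers name no unit. There are 29639 genes in the mRNA table and 29158 long non-coding transcripts. The deposited microRNA values are RPM: each column sums to the same total, and 100% of values were whole multiples of the value of 1 read to within 0.02 of a read, so whole reads were recovered for 2395 small RNAs. The labels hold 8 samples, 2 per group, and each table has 4 columns, which carry a group name and no replicate number.

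Of the mRNA entries 22036 had an Ensembl gene ID and 22022 of these were matched to a symbol; 7603 are the authors' newly assembled genes and 14 IDs had no symbol. Values of 40 entries that share 20 symbols were summed. Long non-coding transcripts (8244 with Ensembl IDs and 20914 assembled) were not matched to names. Features were kept at 1 FPKM or more (mRNA), 0.5 FPKM or more (long non-coding) or 10 RPM or more (microRNA) in at least 2 columns, which left 13279, 6181 and 505. Differences are on the log2(value + 0.5) scale, which understates folds of low genes. Gene positions are RefSeq spans on the same build, GRCm38.

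The design fixed limma with 2 libraries per group; with 1 column per group no spread within groups can be estimated and that model could not be fitted. Each comparison was therefore described by the number of features past 2-fold, without p-values. The comparisons were PKI, MKI and HOMO against WT, HOMO against MKI, MKI against PKI, HOMO against PKI, the maternal and paternal effects and their interaction. The comparisons, gene lists, filters and pseudocount were chosen before the data were examined, except that HOMO against PKI was not among the comparisons fixed for counts of genes. The 2-fold threshold was set once the number of columns was known. The fixed rule for named genes needed adjusted p-values and replicates. In its place the 10 largest differences each way against WT and in the maternal effect were named (at least 2-fold and 2 FPKM in the higher column, with a gene symbol), 5 for long non-coding transcripts (1 FPKM; at most 2 identifiers each way are printed) and 5 for microRNAs outside the domain (50 RPM), with the 6 domain microRNAs highest in WT, up to 4 members per list with the largest differences, the paternally expressed domain genes, and flanking genes past 2-fold. Other members are given as examples and were chosen after their values were seen.

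Lists covered the domain (maternal RNAs, paternal genes, flanking genes, microRNAs by number), other imprinted genes, hepatocytes, definitive and embryonic red cells, blood progenitors, endothelium, mural cells, hypoxia, skeletal and heart muscle, neural progenitors, neurons, cartilage, matrix, epidermis, cell division, p53 targets, macrophages, interferon response, Notch, thyroid hormone, the insulin-like growth factor axis, yolk sac, placenta, mitochondrial and ribosomal transcripts, immediate early genes, sex-linked genes and microRNAs of 5 tissues and of flanking sites. A list with at least 5 measured members was placed by the percentile of its median among 10000 random lists of the same size, matched on mean expression in 25 bins (seed 1); 24 lists were placed. Shares of reads have exact Clopper-Pearson 95% intervals and ratios of reads exact conditional 95% intervals. Both cover counting error only.

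Alternatives were a pseudocount of 0.1 or 1, no filter, a stricter filter (5 FPKM, 2 FPKM and 100 RPM), quantile normalization and TMM factors. Added after seeing the data were RPM over microRNAs outside the domain, single backgrounds alone, limma with additive maternal and paternal terms, an exact binomial test on the recovered reads, pairs of comparisons that share no column, and random lists matched on RefSeq gene span as well as expression (5 bins of each, for lists with a span for at least 80% of members). Steps were tested on simulated data. For PKI against WT over 13279 mRNA genes, a list of 25 genes shifted by -1 was recovered at -0.999, and 5% of unshifted lists fell outside the central 95%. The simulated genes varied independently of each other, whereas genes of a list can vary together. List percentiles therefore give a place among random lists and no error rate. Under a simulated trend with span, 10.5% of unshifted lists of long genes fell outside with lists matched on expression and 7% with lists matched on both, over 12539 genes. For MKI against WT, 6% of 200 genes altered 1.5-fold, 99% of those altered 3-fold and 99.5% of those altered 4-fold passed 2-fold, against 0.0535% of unaltered genes at 1.5-fold. The simulated spread was taken from PKI against WT, whose log2 quartiles were -0.263 and 0.125. Those of MKI against WT were -0.789 and 0.328, so these rates do not describe the MKI column. Intervals held the simulated ratio for 96.7% of 300 microRNAs. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.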

Results

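RNA was profiled in whole mouse embryos of 4 genotypes at embryonic day 12.5, per the design text of the series. Wild-type embryos (WT) were compared with embryos in which 3 polyadenylation cassettes, sequences that end a transcript early, had been placed in the Gtl2 promoter. Gtl2, also called Meg3, is the first of a chain of non-coding RNAs made from the maternal copy of the imprinted Dlk1-Dio3 domain on chromosome 12. Dlk1, Rtl1 and Dio3 are the protein-coding genes read from the paternal copy of the same domain. The insertion was inherited from the father (PKI), from the mother (MKI) or from both parents (HOMO), and the comparisons ask how the RNAs of the domain and of the rest of the genome differ when either or both copies carry it.

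The labels describe 8 libraries, 2 per genotype, whereas each of the 3 deposited tables holds 1 column per genotype. There are therefore no replicates, and every difference given here is between single columns. The sample titles give a slightly different embryonic day for each genotype, earliest for WT and latest for HOMO, while the design text gives 12.5 for all. The small-RNA table gave whole reads back from its values, 8405962 in WT, 10072670 in PKI, 8638401 in MKI and 8016848 in HOMO. Among microRNAs 3 reads, the limit that a count of 0 allows, correspond to between 0.298 and 0.374 rpm, reads scaled to a common total per column. The depth behind the 2 long-RNA tables, which hold FPKM, is unknown. Of 29639 genes in the mRNA table, 21190 had a value above 0 in WT, 21036 in PKI, 19885 in MKI and 20758 in HOMO. Across 13279 mRNA genes, which are not independent replicates, Pearson's r between the log2 columns was 0.970 for WT and PKI, 0.975 for WT and HOMO and 0.961 for PKI and HOMO, but between 0.864 and 0.882 for MKI with each of the others. The Y-linked genes Uty, Eif2s3y, Ddx3y and Kdm5d were listed at 0 in WT and lay between 7.12 and 29.7 FPKM in the other 3 columns.

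The domain was considered first, because the insertion lies in it. Meg3 itself (chromosome 12, 109540996 to 109571729, GRCm38) was not analysed here, since none of the 13 maternal long RNAs listed in advance was matched by name, and the microRNAs processed from the maternal transcripts downstream of it were used instead. They were far lower in both columns from embryos that inherited the insertion from the mother. Domain microRNAs made up 13.7% of microRNA reads in WT (exact binomial 95% interval 13.69 to 13.73%) and 12.5% in PKI (12.47 to 12.51%), against 0.408% in MKI (0.404 to 0.412%) and 0.426% in HOMO (0.421 to 0.430%). These intervals, and all others on reads, cover counting error only. All 77 domain microRNAs above the expression filter were more than 2-fold lower than WT in MKI and in HOMO, with median log2 differences of -4.86 (range -7.25 to -3.43) and -4.82 (range -6.88 to -2.54). In PKI none of them passed 2-fold, and the median was -0.02 (range -0.93 to 0.60).

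The 6 domain microRNAs most abundant in WT showed the size of the difference. miR-127-3p, processed from a precursor at 109592846 to 109592915 that lies antisense to Rtl1 within the Rtl1 span, stood at 26481, 26139.5, 455 and 794 rpm in WT, PKI, MKI and HOMO, so that MKI held 1.72% (1.66 to 1.77%) of the WT level and HOMO 3.00% (2.92 to 3.07%). In the same order of columns miR-541-5p stood at 19152, 23305, 965 and 549 rpm, and miR-434-5p at 13281, 7642, 294 and 336 rpm. miR-370-3p, from the Rian span, held 3.67% (3.55 to 3.80%) of WT in MKI and 3.67% (3.54 to 3.80%) in HOMO, while miR-381-3p held 2.50% (2.40 to 2.60%) and 3.40% (3.28 to 3.53%), and miR-379-5p, the first precursor of the large distal cluster, held 2.70% (2.58 to 2.83%) and 3.36% (3.22 to 3.51%). Over the 79 domain microRNAs with at least 100 WT reads the median was 2.70% of WT in MKI, with a range from 0 reads for miR-1188-5p (interval up to 3.14% of WT) to 8.84% for miR-376c-3p, and 3.36% in HOMO, with a range from 0.303% for miR-673-5p to 16.0% for miR-376b-5p. In PKI the median was 98.0%, and single microRNAs lay on both sides, from 37.6% for miR-341-5p to 151% for miR-494-3p. Counting intervals of the ratio to WT lay wholly below 100% for 30 of the 79 in PKI and wholly above for 30.

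**Figure D1:**
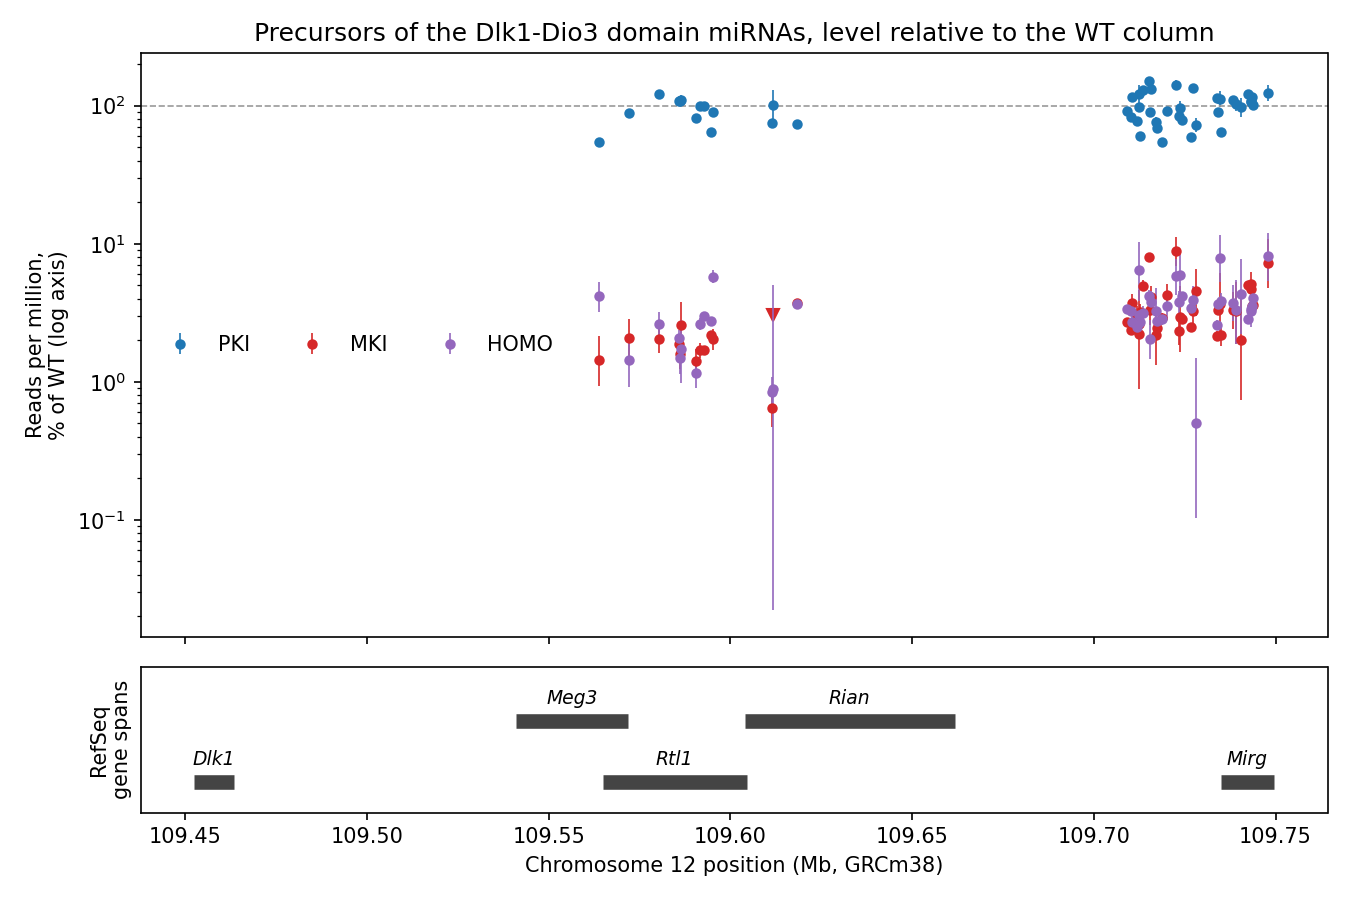
Reads per precursor as a percent of WT (log axis) along chromosome 12 (Mb, GRCm38) for PKI, MKI and HOMO, with 95% counting intervals as bars, a downward triangle at the upper limit for a precursor without reads in MKI, and the RefSeq spans of Dlk1, Meg3, Rtl1, Rian and Mirg below. The 49 precursors lie around 97.8% of WT in PKI (median) and around 2.83% in MKI and 3.28% in HOMO.

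Set directly against each other, HOMO and PKI differed in the domain microRNAs by a median log2 of -4.74, MKI and PKI by -4.75, and HOMO and MKI by 0.16, where 8 passed 2-fold upward in HOMO and 2 downward. The median for HOMO and MKI was 0.023 under quantile normalization and 0.019 under scaling by trimmed means of log ratios (TMM). The mean over both paternal backgrounds, (MKI + HOMO)/2 minus (WT + PKI)/2, hereafter the maternal effect, was -4.79. The corresponding paternal effect, (PKI + HOMO)/2 minus (WT + MKI)/2, was 0.06, and it changed sign to -0.018 under TMM scaling. Among 10000 random microRNA sets matched on expression no set had a median as low as that of the domain in MKI or HOMO against WT. The 5 microRNAs encoded near but outside the domain did not pass 2-fold in any knock-in column, with medians of 0.14 in PKI, 0.18 in MKI and 0.01 in HOMO against WT.

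Among the paternally expressed genes, Dlk1, a transmembrane protein related to Notch ligands (chromosome 12, 109452485 to 109463336), stood at 80.5, 55.7, 83.4 and 181 FPKM in WT, PKI, MKI and HOMO. It was thus 1.17 on the log2 scale above WT in HOMO and near WT in MKI (0.05), and lower in PKI (-0.53). Rtl1, a retrotransposon-derived gene with roles in placental vessels (109564900 to 109604418), was higher than WT in both columns with a maternal insertion, at 1.02, 0.610, 2.28 and 2.51 FPKM in the same order (log2 differences -0.46, 0.87 and 0.98). Dio3, the deiodinase that inactivates thyroid hormone (110279230 to 110281097), lay below the expression filter at 0.568, 0.416, 0.217 and 1.42 FPKM. Of the 15 measured genes next to the domain, none was 2-fold away from WT in PKI or HOMO (medians -0.09 and -0.05, the latter of the opposite sign under quantile normalization and TMM scaling). In MKI 3 were more than 2-fold lower, Slc25a29 (0.814 against 2.62 FPKM), Begain (1.07 against 3.21 FPKM) and Zfp839 (1.29 against 3.14 FPKM). The MKI column stood apart from the others across the whole mRNA table.

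**Figure D2:**
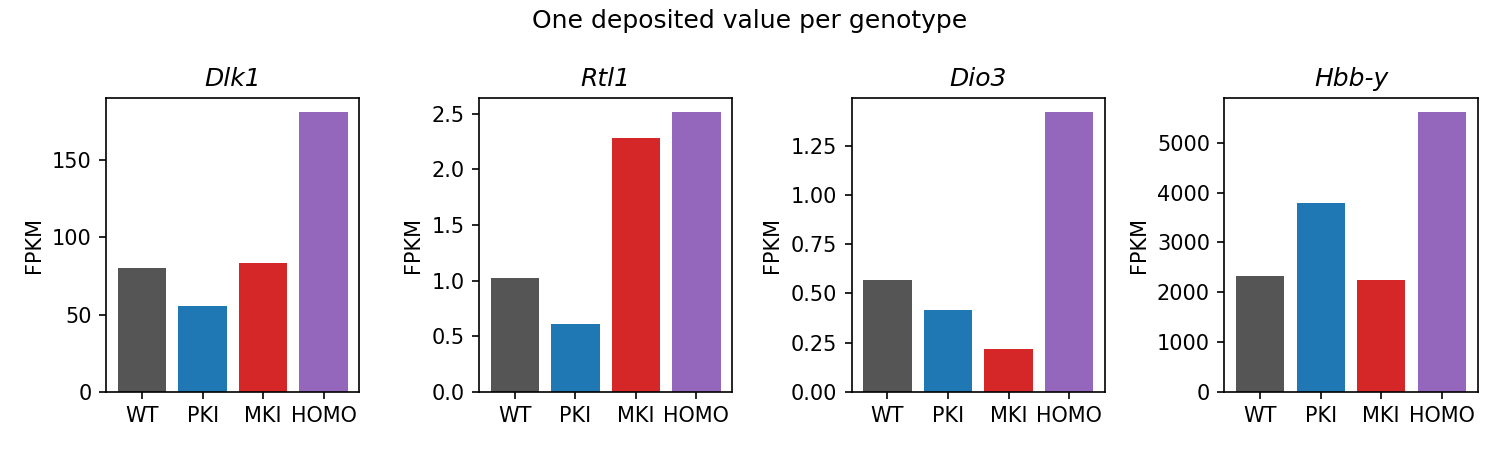
FPKM (bars, linear axes from 0, 1 value per column) of the paternally expressed domain genes Dlk1, Rtl1 and Dio3 and of the embryonic globin gene Hbb-y in WT, PKI, MKI and HOMO. Dlk1 was 181 FPKM in HOMO against 80.5 in WT, and Hbb-y 5619 against 2334.

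Outside the domain few microRNAs passed 2-fold on the deposited scale. Of 428 tested, 4 were 2-fold higher and 8 lower than WT in PKI, 13 and 10 in MKI, and 11 and 9 in HOMO. These 428 are all tested microRNAs not in the domain list, newly named small RNAs of unknown position included. Without the filter on low values the counts over all microRNAs, the domain included, were 105 in PKI, 245 in MKI and 264 in HOMO, many of them from few reads. With the filter and the domain included, 13 were 2-fold higher and 87 lower than WT in MKI, against 115 and 79 under quantile normalization. In HOMO they were 11 and 86, against 85 and 79. The erythroid mmu-miR-451a was highest in MKI, at 492.9, 647, 1501 and 854 rpm in WT, PKI, MKI and HOMO, which is 305% (294 to 315%) of WT in MKI. mmu-miR-145a-5p, a smooth muscle microRNA, was at 564, 1232, 1265 and 746 rpm, miR-221-5p at 35.1, 50.5, 81.8 and 59.0 rpm, miR-501-5p at 32.0, 46.9, 72.8 and 40.8 rpm, and miR-19b-3p of the miR-17-92 cluster at 369.3, 549.5, 791 and 491 rpm. In HOMO the largest difference among higher microRNAs was in mmu-miR-29a-3p, at 38.4, 37.7, 54.2 and 463 rpm, or 1204% (1074 to 1353%) of WT, followed by a newly named small RNA, novel_miR_205, at 9.99, 19.5, 11.6 and 61.6 rpm. The pluripotency-associated miR-292a-5p stood at 23.9, 34.0, 41.3 and 83.0 rpm and miR-219a-5p at 71.0, 76.5, 95.6 and 151 rpm. In PKI miR-615-3p, encoded in the Hoxc cluster, was 1961 against 4336 rpm, miR-708-3p 302 against 609 and miR-1298-5p 313 against 627. miR-3963 was higher, at 80.6 against 33.4 rpm.

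Several microRNAs that are not in the domain list were low in both columns with a maternal insertion. The newly named small RNA novel_miR_531 was at 239, 206.4, 9.49 and 9.98 rpm in WT, PKI, MKI and HOMO, and novel_miR_780 at 20.7 rpm in WT and 1.12 rpm in HOMO. miR-375-3p, an endocrine microRNA, was at 117, 107, 36.0 and 41.7 rpm, miR-301b-5p at 334, 225, 113 and 131.97 rpm, miR-219a-1-3p at 153, 164, 51.9 and 66.9 rpm, miR-598-3p at 322, 385, 127.9 and 125 rpm and miR-30e-3p at 1161, 1002, 454 and 476 rpm. Of these miR-301b-5p was less than 2-fold lower in HOMO than PKI. Together with miR-30a-3p (1076, 1111, 439 and 519 rpm) and novel_miR_307, and without miR-301b-5p, 8 microRNAs not in the domain list were 2-fold lower both in MKI than WT and in HOMO than PKI. These pairs share no column, and independent lists of these sizes would share 0.257. The newly named small RNAs among the 8 carry no microRNA number, so whether they lie in the domain is unknown. No microRNA outside the domain list was 2-fold higher in both pairs. With the sign of a pair reversed, PKI against WT and MKI against HOMO shared 2 lower where independent lists would share 0.15.

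The tissue microRNA lists lay closer to WT. Median log2 differences from WT for PKI, MKI and HOMO were 0.20, 0.11 and 0.56 for 6 erythroid microRNAs, 0.15, 0.21 and 0.29 for 7 muscle microRNAs and -0.11, -0.16 and 0.21 for 10 neural microRNAs. For 5 liver microRNAs they were -0.41, 0.15 and 0.43, and for 8 endothelial and blood microRNAs -0.11, 0.19 and 0.39. miR-122-5p, which is made almost only by hepatocytes, stood at 3587, 2695, 3979 and 4869 rpm in WT, PKI, MKI and HOMO. Values of these lists are relative to all microRNA reads, of which the domain takes a smaller part in MKI and HOMO; rescaling to reads outside the domain moves the median microRNA by -0.21 on the log2 scale in both columns, and quantile normalization moves it by 0.66 in MKI and 0.52 in HOMO.

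The comparison of PKI with WT asks what a paternally inherited insertion, on the copy that does not normally make Meg3, goes with. Genes of the fetal liver were lower in PKI. All 25 measured hepatocyte genes, which yolk sac endoderm also expresses, lay below their WT level and 18 were more than 2-fold lower (median log2 difference -1.33, percentile 0 among 10000 random lists matched on expression, whose central 95% spanned -0.19 to 0.08). Examples were Afp, the fetal serum carrier protein, at 96.2 FPKM against 292, Alb, encoding albumin, at 81.1 FPKM against 205, and Ahsg (1.53 against 5.94 FPKM). Among the genes with the largest differences, transferrin (Trf) was at 24.1 FPKM against 85.1, Ambp at 4.13 FPKM against 16.0, Apoh at 0.335 FPKM against 2.27 and Serpina1b, a member of a family of near-identical copies and therefore uncertain, at 1.66 FPKM against 16.8.

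Blood and vessel genes were lower as well. Of 23 definitive erythroid genes 22 were below WT and 10 more than 2-fold (median log2 difference -0.95, percentile 0), among them the transcription factor gene Gata1 (1.70 against 5.49 FPKM), the spectrin gene Sptb (3.97 against 10.3 FPKM) and the erythropoietin receptor gene Epor (2.74 against 6.96 FPKM). Pklr, the red cell and liver pyruvate kinase, was 4.41-fold lower (3.43 against 16.8 FPKM). The adult-type globins Hbb-bs and Hba-a2 stood at 1123 and 806 FPKM against 2201 and 1528, whereas the embryonic globin Hbb-y, made in yolk-sac-derived red cells, was higher at 3798 FPKM against 2334. Globins are close copies of each other and their split is uncertain. Progenitor genes (10 measured, median log2 difference -0.56, percentile 0.07) included Itga2b (0.726 against 2.83 FPKM), Myb (2.00 against 3.93 FPKM) and Gfi1b (0.674 against 3.40 FPKM), a repressor needed for red cell and platelet formation. Of 25 endothelial genes 22 were below WT (median log2 difference -0.42, percentile 0), with Vwf, the clotting factor of vessel walls, at 1.56 FPKM against 3.06 and Kdr, the main VEGF receptor, at 6.24 FPKM against 11.7.

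Cartilage and neuronal genes were also lower in PKI. All 16 cartilage and early bone genes were below WT, 4 of them more than 2-fold (median log2 difference -0.76, percentile 0), including the collagen gene Col2a1 (27.8 against 68.0 FPKM) and the proteoglycan gene Acan (0.783 against 2.36 FPKM). All 26 neuronal genes were below WT (median log2 difference -0.62, percentile 0), with the neurofilament-type gene Ina (26.9 against 55.6 FPKM) and Dcx (26.4 against 54.2 FPKM), a marker of young neurons. Notch pathway genes (18 of 22 below WT, median log2 difference -0.47, percentile 0) included Notch1 (14.6 against 24.5 FPKM), and neural progenitor genes (15, median log2 difference -0.38, percentile 0.12) included Olig2 (0.579 against 1.37 FPKM). Matrix genes of mesenchyme (21, median log2 difference -0.23, percentile 0) lay on both sides, fibronectin Fn1 at 40.9 FPKM against 78.0 and lumican Lum at 59.3 FPKM against 32.9. Genes of the giant sarcomere proteins were lower, Ttn at 2.95 FPKM against 10.8 and Neb at 1.63 FPKM against 4.05, while the 23 skeletal muscle genes had a median of -0.19 (percentile 5.99). Long genes were lower in PKI in general, with a Spearman's rho of -0.286 between the log2 difference and the gene span across 12539 genes, which are not independent replicates. With random lists matched on span as well as expression, 12 of the 14 lists outside the central 95% in PKI against WT stayed outside, cartilage (percentile 0), neuronal (0), matrix (0.1), hepatocyte (0) and definitive erythroid genes (0) among them, and skeletal muscle genes came to lie outside (2.43).

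Epidermal genes were higher in PKI, with 15 of 17 above WT and 5 more than 2-fold (median log2 difference 0.87, percentile 100). The basal keratin genes Krt5 and Krt14 stood at 32.4 and 15.0 FPKM against 13.6 and 7.23, and Trp63, the master regulator of stratified epithelium, at 6.29 FPKM against 2.55. Heart genes were slightly higher (15 genes, median log2 difference 0.16, percentile 99.7), with Nppa (18.0 against 10.3 FPKM) and Myl7 (24.9 against 15.5 FPKM), as were ribosomal protein genes (28 of 29 above WT, median log2 difference 0.39, percentile 99.97), whose spans are short and whose percentile was 99.24 among lists also matched on span. Single genes with large differences included Sumo2, 27.3-fold higher (113 against 3.68 FPKM), Rps27rt (4.89-fold) and Hist2h2aa1 (4.60-fold), all 3 with close copies elsewhere in the genome and so uncertain, besides Capn11 (3.00 against 0.0807 FPKM), the zinc finger gene Zfp146 (5.25 against 0.831 FPKM) and the granulocyte gene S100a8 (4.30 against 0.993 FPKM). The histone gene Hist1h3d was 23.8-fold lower and Hist1h2bj 5.84-fold lower, both uncertain for the same reason, and Duxbl1 (0.272 against 2.99 FPKM) was also lower.

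In all, 93 of 13279 genes were 2-fold higher and 193 lower in PKI than WT, so that 32.5% of them were higher, against 48.9% under quantile normalization. Medians of 2 further lists lay below the central 95% of lists matched on expression but within that of lists also matched on span, -0.11 for 32 imprinted genes outside the domain (percentile 1.54, and 11.54 with span) and -0.38 for 5 thyroid hormone genes (2.13, and 2.77). Medians of the remaining lists lay within, at 0.08 for 12 mural cell genes (percentile 94.61), -0.09 for 24 hypoxia-inducible genes (13.92), 0.01 for 27 cell division genes (54.07), 0.05 for 18 p53 target genes (93.52) and 0.05 for 16 macrophage genes (96.88). For 17 insulin-like growth factor genes the median was -0.05 (31.47), for 11 immediate early and heat shock genes -0.15 (36.06) and for 13 mitochondrial transcripts -0.00 (3.61); the first and the last change sign under TMM scaling and the second under quantile normalization. Across all genes the median was -0.07. The Y-linked genes were listed at 0 in WT and above 0 in PKI, so that the columns also differ in Y-linked expression. The number of genes past 2-fold was 466 with a pseudocount of 0.1 and 185 with a pseudocount of 1.

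The comparison of MKI with WT asks what a maternally inherited insertion goes with, when the paternal copy is intact. As many as 2532 mRNA genes were more than 2-fold lower and 162 higher, far more than in PKI (193 and 93) or HOMO (104 and 89). Under quantile normalization 1462 were lower and 656 higher in MKI. Short genes were lower in general, with a Spearman's rho of 0.350 between the log2 difference and the gene span across 12539 genes. The lowest genes included 6 histone genes, which are short and whose transcripts mostly lack the poly(A) tail used to select RNA, Hist1h2ai at 3.93 FPKM against 189, Hist1h2af at 19.7 FPKM against 440.2, Hist1h2ae at 5.63 FPKM against 166, Hist1h2ag at 4.45 FPKM against 93.2, Hist1h2ac at 0.772 FPKM against 39.2 and Hist4h4 at 3.23 FPKM against 85.8. No list of histone genes was fixed, Hist1h3d (167 against 23.8 FPKM) and Hist2h2aa1 (90.8 against 62.2 FPKM) were higher, and how reads were split among such near-identical copies is uncertain. Ccnb1ip1, encoding an E3 ligase that regulates cyclin B (chromosome 14, 50789249 to 50795728), stood at 1012, 2339, 2.21 and 1.24 FPKM in WT, PKI, MKI and HOMO, 373-fold lower than WT in MKI and 583-fold lower in HOMO. The highest value of any mRNA entry was 3529 FPKM in WT and 3798 FPKM in PKI. Whether reads were assigned rightly to Ccnb1ip1 at such levels was not checked. Arf6 (26.3 FPKM in WT), Blcap (26.1) and Raver1 (8.81), each detected in the other 3 columns, were listed at 0 in MKI. Blcap overlaps the imprinted gene Nnat on chromosome 2.

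By list, Notch pathway genes were lower (20 of 22 below WT and 11 more than 2-fold, median log2 difference -1.06, percentile 0.01), with the receptor gene Notch3 (7.06 against 26.5 FPKM), the effector gene Hes5 (2.99 against 21.9 FPKM) and the ligand gene Dll3 (1.54 against 6.07 FPKM). Matrix genes were lower as a list (21 genes, 4 more than 2-fold, median log2 difference -0.52, percentile 0.93), with Mfap4 (15.5 against 40.3 FPKM) and Col5a1 (7.23 against 23.7 FPKM). Transcripts of the mitochondrial genome were higher (12 of 13 above WT, 4 more than 2-fold, median log2 difference 0.61, percentile 99.91), with mt-Nd1 (355 against 96.1 FPKM) and mt-Co1 (3969 against 1936 FPKM). These 3 lists lay outside the central 95% of lists matched on expression, against 5 lists under the stricter filter. Notch (0.33) and matrix genes (0.06) stayed outside with lists also matched on span, which could not be done for the mitochondrial list. Random lists of matched genes also lay low in MKI, with a central 95% of -0.72 to 0.16 for those matched to endothelial genes. Other lists with many members more than 2-fold lower were endothelial genes (7 of 25, median log2 difference -0.67, percentile 4.11), such as Cldn5 (1.99 against 7.48 FPKM), Esam (1.46 against 6.44 FPKM) and Sox18 (1.20 against 4.35 FPKM), and mural cell genes (5 of 12, median log2 difference -0.44, percentile 17.72). p53 targets had 8 of 18 lower (median -0.31, percentile 25.24), with Bax (8.52 against 26.9 FPKM), and ribosomal protein genes 8 of 29 (median -0.34, percentile 13.9), with Rps14 (75.5 against 745 FPKM), but both medians are above 0 under quantile normalization.

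Erythroid genes in MKI were mixed (7 of 23 more than 2-fold lower, median log2 difference -0.37, percentile 14.79), with Epor (1.65 against 6.96 FPKM) and Gata1 (2.52 against 5.49 FPKM) lower and Alas2 (34.1 against 27.9 FPKM) higher. The 25 hepatocyte genes had a median of -0.07 (percentile 61.02), above 0 under quantile normalization and TMM scaling, with Alb at 542 FPKM against 205 and Vtn at 4.68 FPKM against 13.5. Of 32 imprinted genes outside the domain 3 were more than 2-fold lower, among them Nnat (64.2 against 309 FPKM) and Igf2 (170.2 against 379.7 FPKM), and the list's median was 0.24 (percentile 96.71). Igfbp2, an insulin-like growth factor binding protein gene, stood at 7.40 FPKM against 67.8. Higher genes in MKI included Pnp2 (7.90-fold, 6.22 against 0.351 FPKM), Capn11 (2.36 against 0.0807 FPKM, and higher than WT in all 3 knock-in columns), mt-Nd1 (3.68-fold), Adam1a (7.88 against 2.05 FPKM), the meiotic synaptonemal gene Syce2 (23.8 against 7.74 FPKM) and Hist1h3d (6.89-fold, uncertain).

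Remaining list medians in MKI against WT were -0.44 for hypoxia-inducible genes (percentile 7.15), with glycolytic Aldoa (64.4 against 169 FPKM), -0.55 for heart genes (10.37), -0.34 for neural progenitor genes (27.86), 0.16 for neuronal genes (92.11), -0.54 for macrophage genes (18.95) and -0.81 for immediate early genes (3.26). They were -0.48 for blood progenitor genes (23.45), 0.24 for cell division genes (85.01) and -0.26 for thyroid hormone genes (34.41). For cartilage (-0.40, 19.23), epidermis (-0.20, 51.21), skeletal muscle (-0.14, 41.79) and growth factor axis genes (-0.11, 30.11) the median is above 0 under quantile normalization. The median of all genes in MKI relative to WT moves by 0.31 on the log2 scale under quantile normalization and by 0.14 under TMM scaling. The Y-linked genes, at 0 in WT, were above 0 in MKI.

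With the insertion on both copies, HOMO lay closer to WT in the mRNA table than MKI did, with 89 genes 2-fold higher and 104 lower, a majority that turns to 117 and 95 under quantile normalization and 108 and 85 under TMM scaling. Apart from Dlk1 and Rtl1, the embryonic globins Hbb-y (5619 against 2334 FPKM) and Hba-x (1059 against 400.0) were higher in HOMO, as was Hbb-bh1 (374 against 220.2). Hypoxia-inducible genes were slightly higher in 22 of 24 cases (median log2 difference 0.15, percentile 100), with the glucose transporter gene Slc2a1 (43.7 against 29.9 FPKM) and the glycolytic gene Aldoa (200.1 against 169 FPKM). Macrophage genes (13 of 16 above WT, median log2 difference 0.20, percentile 99.93) included Laptm5 (6.23 against 4.29 FPKM), and endothelial genes (median log2 difference 0.17, percentile 100) included Vwf (4.99 against 3.06 FPKM). Neuronal genes were lower in 25 of 26 cases (median log2 difference -0.27, percentile 0), with Gad1 (2.84 against 4.59 FPKM), the enzyme that makes GABA, and Snap25 (4.86 against 6.98 FPKM), a synaptic vesicle fusion gene.

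Sox2, a transcription factor of neural stem cells that lies inside the non-coding gene Sox2ot on chromosome 3, was 8.11-fold lower in HOMO (0.734 against 9.51 FPKM, and 3.21 in PKI and 11.1 in MKI). Ctse was at 0.301 FPKM against 4.59, Zfand1 at 0.442 FPKM against 3.97, Ndufa12, a subunit of respiratory complex I, at 6.44 FPKM against 22.7, Mia at 1.15 FPKM against 3.99, Zfp991 at 0.808 FPKM against 3.31 and Wdfy1 at 5.24 FPKM against 14.7. Rpl29 was 19.3-fold lower and Serpina1b 3.59-fold lower, both with close copies and uncertain. Higher genes were Sumo2 (20.8-fold), Hist2h2aa1 (9.58-fold) and Hist1h3d (4.81-fold), uncertain for the same reason, Zfp146 (20.9 against 0.831 FPKM), Capn11 (2.96 against 0.0807 FPKM) and the tachykinin gene Tac2 (5.10 against 1.34 FPKM).

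Hepatocyte and definitive erythroid genes in HOMO differed little from WT in size, with medians of 0.03 (percentile 95.32) and 0.07 (99.01), Afp at 365 FPKM against 292 and Gata1 at 6.62 FPKM against 5.49. Heart genes had a median of -0.21 (1.93), with Tnnt2 (11.5 against 17.0 FPKM) and Myh6 (6.89 against 10.8 FPKM), and neural progenitor genes -0.22 (0.98). Medians were 0.13 for blood progenitors (98.92), 0.08 for epidermis (98.8), 0.04 for matrix (96.95), 0.02 for mural cells (88.48), 0.08 for ribosomal proteins (99.09), 0.09 for immediate early genes (95.88) and 0.12 for thyroid hormone genes (95.33). They were below 0 for cartilage (-0.19, 3.22), skeletal muscle (-0.09, 31.09), p53 targets (-0.07, 41.81), other imprinted genes (-0.08, 27.4) and mitochondrial transcripts (-0.09, 18.06). Those of the Notch (-0.05, 61.36), cell division (-0.04, 61.47) and growth factor axis lists (-0.03, 63.61) change sign under TMM scaling. With lists also matched on span, epidermal (97.34) and ribosomal protein genes (91.31) came to lie within the central 95% and matrix genes outside (99.11). Y-linked genes were again listed above 0 in HOMO and at 0 in WT. Without a filter on low values 161 genes were 2-fold higher and 184 lower in HOMO, and with a stricter filter 85 passed 2-fold in either direction.

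Lists with fewer than 5 measured members were not set against random lists. Their medians in PKI, MKI and HOMO against WT were 0.70, -0.06 and 1.27 for 3 embryonic globins, 0.01, 0.26 and -0.22 for 4 interferon-stimulated genes, -0.89, -0.84 and -0.22 for 2 yolk sac endoderm genes and 0.25, -0.11 and 0.45 for 3 placental genes. The 4 Y-linked genes had medians of 4.71, 5.08 and 4.39, and neither of the 2 female markers was measured.

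**Figure D3:**
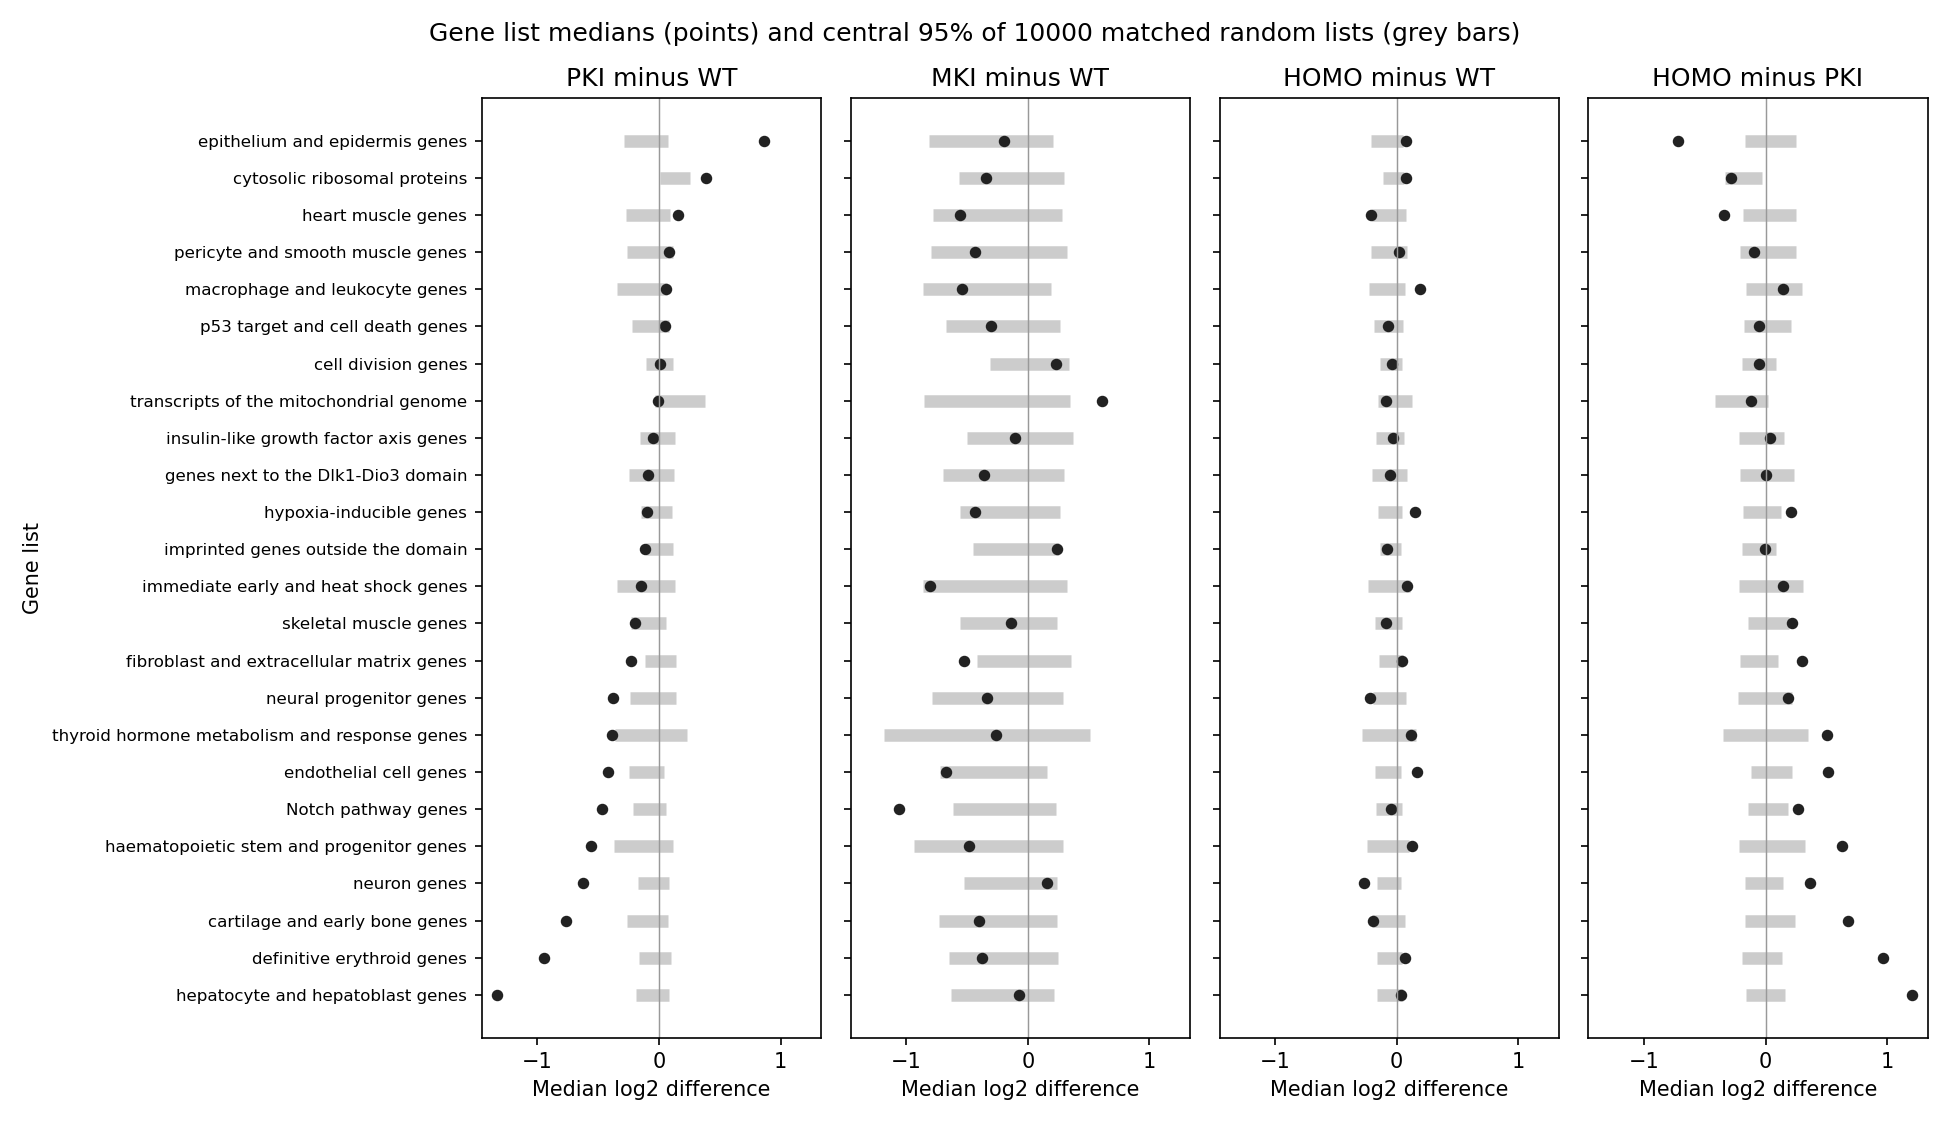
Median log2 difference of each gene list (points) with the central 95% of medians of 10000 expression-matched random lists (grey bars) for PKI, MKI and HOMO against WT and for HOMO against PKI. Hepatocyte genes lie at -1.33 in PKI against WT and at 1.20 in HOMO against PKI, outside the grey bar in both panels, and the MKI medians of cartilage, ribosomal protein, epidermis, p53, hepatocyte, growth factor and skeletal muscle lists turn positive under quantile normalization.

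HOMO and PKI share the paternal insertion and differ in the maternal one, and the Y-linked genes were above 0 in both columns. Most lists that were low in PKI were higher in HOMO than in PKI, although the medians of neural progenitor (0.18, percentile 95.41) and other imprinted genes (-0.0032, 76.42) lay within the central 95%. Among the higher lists, 16 of 25 hepatocyte genes were more than 2-fold higher (median log2 difference 1.20, percentile 100), 11 of 23 definitive erythroid genes (median log2 difference 0.97, percentile 100) and 5 of 16 cartilage genes (median log2 difference 0.68, percentile 100). Alb was at 259 FPKM against 81.1, Trf at 129.3 FPKM against 24.1, Slc4a1, the red cell anion exchanger, at 52.7 FPKM against 23.2, and Col2a1 at 58.1 FPKM against 27.8. Medians were also above 0 for progenitor (0.62, 99.98), endothelial (0.51, 100), neuronal (0.36, 100), matrix (0.30, 100), thyroid hormone (0.50, 99.63), Notch (0.27, 99.83), skeletal muscle (0.22, 98.51) and hypoxia-inducible genes (0.21, 99.89), and below 0 for epidermal (-0.72, 0) and heart genes (-0.34, 0.07). In all 1.55% of genes were 2-fold higher and 1.32% lower. Because PKI enters both this comparison and that with WT, opposite signs of a list in the 2 comparisons can arise from the PKI column alone.

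MKI differed from the other knock-in columns about as much as from WT. Against MKI, 2615 genes were 2-fold higher in HOMO and 484 lower, and against PKI 339 were higher in MKI and 2198 lower. Under quantile normalization the splits were nearer to balance, 1724 and 1093 in the first comparison and 745 and 1461 in the second. The maternal effect passed 2-fold upward in 51 genes and downward in 473. It was downward for Ccnb1ip1 (709-fold), Rpl29 (6.53-fold) and the histone genes Hist1h2ae (8.93-fold), Hist1h2ac (8.61-fold), Hist1h2an (7.29-fold), Hist1h2af (7.23-fold), Hist4h4 (6.80-fold), Hist1h2ag (6.20-fold), Hist1h2ah (5.54-fold) and the linker histone gene Hist1h1c (4.99-fold), with histone and ribosomal protein genes uncertain as copies. It was upward for Hist1h3d (28.1-fold), the Y-linked Eif2s3y (7.89-fold), the platelet chemokine gene Ppbp (3.08-fold), Zfp708 (3.07-fold), the neural transcription factor gene Pou3f3 (3.06-fold), mt-Nd1 (2.85-fold) and the liver genes Alb (2.90-fold), Itih3 (2.74-fold), Trf (2.60-fold) and Afp (2.43-fold). Eif2s3y, at 0, 14.4, 29.7 and 14.9 FPKM in WT, PKI, MKI and HOMO, shows that the maternal effect also carries the lack of Y-linked RNA in the WT column. For Trf and Afp PKI was the lowest column, at 85.1, 24.1, 109 and 129.3 and at 292, 96.2, 457 and 365 FPKM in the same order, and the hepatocyte list had a median of -0.07 in MKI against WT. The paternal effect passed 2-fold upward in 413 genes and downward in 50. The MKI column, with 2532 genes 2-fold below WT, enters the maternal and paternal effects with opposite signs. Its low values therefore lower the first and raise the second. In PKI against WT alone 93 genes were 2-fold higher and 193 lower, the opposite majority to that of the paternal effect. The interaction, (HOMO minus MKI) minus (PKI minus WT), passed 2-fold upward in 3159 genes and downward in 797, or 2054 and 1653 under quantile normalization.

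A pair of comparisons of the maternal insertion, MKI with WT and HOMO with PKI, use 4 different columns and so share no chance value. Of the mRNA genes, 13 were 2-fold higher in both, where independent lists would share 2.51, among them Alb, Pou3f3, Zfp708, mt-Nd1 and the tropomyosin gene Tpm3. Another 61 were 2-fold lower in both against 33.4, among them Ccnb1ip1, several histone genes, Krt14, the mitochondrial protein gene Chchd2 and Atp5g1, a subunit of ATP synthase. These members beyond the largest differences were chosen after their values were seen. Across all mRNA genes, which are not independent replicates, Pearson's r between the 2 log2 differences was -0.114; across microRNAs it was 0.921 (Spearman's rho 0.385) with the domain and 0.264 (rho -0.0057) outside it, with 85 microRNAs 2-fold lower in both against 15.2 for independent lists. For the paternal insertion, PKI with WT and HOMO with MKI, 26 genes were 2-fold higher in both (18.3 if independent) and 11 lower (7.03), with r = -0.0427. With the sign of a pair reversed, a direction that no like effect of the insertion predicts, PKI against WT and MKI against HOMO shared 12 higher genes (3.39 if independent) and 50 lower (38.0), so an excess over independent mRNA lists is no measure of a shared effect.

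Long non-coding transcripts are listed by identifiers that the sources used here do not pair with gene names, so domain members among them are not named. Of 6181 tested, 187 were 2-fold higher and 214 lower than WT in PKI, 402 and 387 in MKI, and 185 and 321 in HOMO. ENSMUST00000182981 was low in both columns with a maternal insertion, at 25.8, 36.0, 0.152 and 0.0869 FPKM in WT, PKI, MKI and HOMO, and MSTRG.10992.2 was listed at 0 in WT and PKI but at 13.4 FPKM in MKI and 5.24 in HOMO. Both maternal pairs gave 97 transcripts 2-fold lower, against 16.6 for independent lists, and 39 higher against 11.4. The paternal pairs gave 59 lower against 25.9 and 57 higher against 9.08, and with the sign of a pair reversed, PKI against WT and MKI against HOMO gave 40 lower against 10.4 and 52 higher against 22.6, so that overlaps beyond independent lists also arose where no like effect predicts them. HOMO against MKI gave 300 higher and 748 lower, MKI against PKI 526 and 362, and HOMO against PKI 175 and 265. The maternal effect gave 116 and 182 and the paternal effect 110 and 182. Counts past 2-fold depend on the pseudocount, with 893 transcripts in PKI, 1443 in MKI and 1064 in HOMO at 0.1 and 176, 385 and 231 at 1. The majority direction turns with the scaling in several of these comparisons. The percent higher among transcripts past 2-fold, as deposited and then under quantile normalization and TMM scaling, was 46.6, 53.6 and 54.7 for PKI against WT and 51.0, 43.4 and 33.5 for MKI against WT. It was 36.6, 54.2 and 49.5 for HOMO against WT, 28.6, 59.4 and 64.6 for HOMO against MKI, 59.2, 41.2 and 32.4 for MKI against PKI, and 37.7, 59.5 and 64.7 for the paternal effect. The median transcript in MKI relative to WT moves by -0.20 on the log2 scale under quantile normalization and by -0.22 under TMM scaling, and in HOMO by 0.21 under each.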

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

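Of the tests in this part, those of a shared maternal effect on mRNA, of a like paternal effect, of embryo sex and of the share of liver were chosen only after the result was seen. Results are listed where the same added allele went in opposite directions on its 2 backgrounds by at least 0.5 on the log2 scale each way. With 1 column per group, in each case the difference was not tested.

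For Dlk1 the paternal knock-in went with a log2 difference of -0.53 in PKI against WT and of 1.11 in HOMO against MKI, 1.64 apart. Dio3, below the expression filter, stood at -0.58 in MKI against WT and at 1.07 in HOMO against PKI for the maternal knock-in, also 1.64 apart. The 25 endothelial genes had medians of -0.67 and 0.51 for the maternal knock-in, 1.18 apart. For the paternal knock-in, the 23 definitive erythroid genes had medians of -0.95 in PKI against WT and 0.51 in HOMO against MKI, 1.46 apart, and the 10 blood progenitor genes -0.56 and 0.60, 1.16 apart. Each of the 5 results uses the MKI column on 1 side. On that side the medians of all the lists named here lay within the central range of matched random lists. That range was -0.72 to 0.16 for endothelial genes in MKI against WT. In HOMO against MKI it was -0.35 to 0.67 for definitive erythroid and -0.42 to 0.96 for blood progenitor genes. The opposite signs of these lists therefore rest on medians that random lists also reach.

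The MKI mRNA column stands apart, with 2532 genes more than 2-fold below WT. A maternal knock-in acting alike on both paternal backgrounds is argued against, since the median of these genes in HOMO against PKI was 0.10 and 38.8% of them lay below 0. The share 2-fold lower there, 2.41%, could not decide, because only 175 of all genes were 2-fold lower in HOMO than PKI. The 61 genes lower in both compare with 33.4 for independent lists. Scaling by a few abundant genes is argued against too, since 2436 genes, in both directions together, still passed 2-fold under TMM factors. A loss of RNA from short genes may contribute: Spearman's rho of the MKI difference with gene span was 0.350 across 12539 genes, which are not independent replicates, and 36.5% of the 3135 genes with the shortest spans (median 5.37 kb) were 2-fold lower against 5.52% of the 3135 with the longest (114 kb). This and an effect specific to MKI embryos cannot be told apart, because rho was also -0.286 in PKI against WT and -0.153 in HOMO, and because genotype and column are the same thing here.

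In PKI, liver and definitive red cell genes were lower. A paternal knock-in acting alike with and without the maternal one is argued against by the hepatocyte median of 0.19 in HOMO against MKI (-0.01 under quantile normalization), within the central 95% of random lists (-0.32 to 0.65), with the caveat that MKI stands apart. Embryo sex is argued against by the median of 0.033 in HOMO against WT, which also differ in Y-linked genes. A smaller share of liver in the PKI material may account for part of the liver pattern: miR-122-5p, from the microRNA table, was at 75.1% of WT (73.9 to 76.4%), an interval that straddles the 75% set as the bound for this explanation, while Afp was at 96.2 against 292 FPKM and Alb at 81.1 against 205 FPKM. For red cells the same table gave no single direction. There miR-451a was higher in PKI (647 against 492.9 rpm), and the 6 erythroid microRNAs ranged from -0.74 to 0.39 (median 0.20). This list does not separate definitive from embryonic red cells, and the embryonic globin Hbb-y was higher in PKI, so it cannot decide for the definitive genes. A smaller liver share in the tissue taken, a difference in stage and a true effect in PKI embryos stay open, because each genotype is 1 column; all 25 list genes were measured in these embryos and 1 is also held by another list.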

How the results depend on the processing

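The alternatives with additive limma terms, single backgrounds, RPM outside the domain, the exact test on reads, pairs sharing no column and lists matched on gene span were chosen after seeing the data; the others were set in advance. No result changed sign past its threshold. Within 1.5 times of the reported count, or within its range, stayed 101 of 177 counts, 25 of 49 domain medians, 970 of 987 list medians and 763 of 908 named features. Domain medians in MKI and HOMO against WT lay between -5.21 and -4.06 under every alternative run. Not run, because each group has 1 column: limma as designed with or without a prior trend, fits of the compared groups only, a replicate block, a sex covariate, each replicate left out, set tests across replicates and a split of the WT libraries. No paired analysis was possible because the columns carry no replicate number. Depth limits only the microRNA table by a known amount, 3 reads being 0.298 to 0.374 RPM. Counts past 2-fold are given as percents of all 29619 genes, 29158 long non-coding transcripts or 2395 small RNAs of a table, a base that no setting alters, with values as reported in parentheses.

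With a pseudocount of 0.1, mRNA genes past 2-fold made up 1.57% for PKI against WT (0.966%) and 2.63% for the paternal effect (1.56%). Long non-coding transcripts past 2-fold made up 3.06% for PKI against WT (1.38%), 4.95% for MKI against WT (2.71%), 3.65% for HOMO against WT (1.74%), 7.41% for HOMO against MKI (3.59%), 5.95% for MKI against PKI (3.05%), 2.59% for the maternal effect (1.02%), 3.04% for the paternal effect (1.00%) and 7.84% for the interaction (4.36%). The domain median was -5.14 for MKI against WT (-4.86), -5.01 for MKI against PKI (-4.75) and -4.92 for the maternal effect (-4.79). With a pseudocount of 1, mRNA genes past 2-fold made up 0.625% for PKI against WT (0.966%). Long non-coding transcripts past 2-fold made up 0.604% for PKI against WT (1.38%), 1.32% for MKI against WT (2.71%), 0.792% for HOMO against WT (1.74%), 1.56% for HOMO against MKI (3.59%), 1.40% for MKI against PKI (3.05%), 0.470% for the maternal effect (1.02%), 0.456% for the paternal effect (1.00%) and 2.14% for the interaction (4.36%). The domain median was -4.68 for the maternal effect (-4.79). Without a filter on low values, mRNA genes past 2-fold made up 1.16% for HOMO against WT (0.652%). Long non-coding transcripts past 2-fold made up 3.00% for PKI against WT (1.38%), 6.07% for MKI against WT (2.71%), 3.39% for HOMO against WT (1.74%), 7.18% for HOMO against MKI (3.59%), 6.49% for MKI against PKI (3.05%), 1.62% for the maternal effect (1.02%), 1.62% for the paternal effect (1.00%) and 10.9% for the interaction (4.36%). MicroRNAs past 2-fold made up 4.38% for PKI against WT (0.501%), 10.2% for MKI against WT (4.18%), 11.0% for HOMO against WT (4.05%), 6.85% for HOMO against MKI (0.793%), 10.4% for MKI against PKI (4.01%), 6.60% for the maternal effect (3.76%), 1.17% for the paternal effect (0.292%) and 15.6% for the interaction (3.05%). The domain median was -4.58 for MKI against WT (-4.86), -4.57 for HOMO against WT (-4.82), -4.57 for MKI against PKI (-4.75) and -4.60 for the maternal effect (-4.79). Under the stricter filter, which tests fewer features, mRNA genes past 2-fold made up 0.429% for PKI against WT (0.966%), 0.287% for HOMO against WT (0.652%) and 8.87% for the interaction (13.4%). Long non-coding transcripts past 2-fold made up 0.298% for PKI against WT (1.38%), 0.576% for MKI against WT (2.71%), 0.418% for HOMO against WT (1.74%), 0.703% for HOMO against MKI (3.59%), 0.648% for MKI against PKI (3.05%), 0.364% for the maternal effect (1.02%), 0.336% for the paternal effect (1.00%) and 0.748% for the interaction (4.36%). MicroRNAs past 2-fold made up 0.167% for PKI against WT (0.501%), 2.76% for MKI against WT (4.18%), 2.51% for HOMO against WT (4.05%), 0.167% for HOMO against MKI (0.793%), 0% for the paternal effect (0.292%) and 1.29% for the interaction (3.05%). The domain median was -5.21 for MKI against WT (-4.86), -5.03 for HOMO against WT (-4.82), -4.94 for MKI against PKI (-4.75), -4.97 for the maternal effect (-4.79) and -0.0028 for the paternal effect (0.06). Lists outside the central 95% numbered 5 for MKI against WT (3) and 7 for the maternal effect (11). Under quantile normalization, microRNAs past 2-fold made up 1.29% for PKI against WT (0.501%), 8.10% for MKI against WT (4.18%), 6.85% for HOMO against WT (4.05%), 8.18% for MKI against PKI (4.01%) and 6.89% for the maternal effect (3.76%). The domain median was -4.06 for MKI against WT (-4.86), -4.11 for HOMO against WT (-4.82), 0.023 for HOMO against MKI (0.16), -3.93 for MKI against PKI (-4.75) and -4.11 for the maternal effect (-4.79). Lists outside the central 95% numbered 8 for HOMO against MKI (5). Under TMM factors, the domain median was 0.019 for HOMO against MKI (0.16) and -0.018 for the paternal effect (0.06). With RPM over microRNAs outside the domain, the domain median was -5.06 for MKI against WT (-4.86), -5.03 for HOMO against WT (-4.82), -4.93 for MKI against PKI (-4.75) and -4.99 for the maternal effect (-4.79). With random lists also matched on gene span, which leaves out the mitochondrial list, lists outside the central 95% numbered 5 for the maternal effect (11). Limma with additive terms, 1 residual degree of freedom and a trended robust prior gave, at an adjusted p of 0.05, 0.189% of mRNA genes for the maternal effect (1.77%), 0.111% of mRNA genes for the paternal effect (1.56%), 0.309% of long non-coding transcripts for the maternal effect (1.02%), 0.219% of long non-coding transcripts for the paternal effect (1.00%) and 0.0418% of microRNAs for the paternal effect (0.292%). With a plain prior it called 0.209% of mRNA genes for the maternal effect (1.77%), 0.115% of mRNA genes for the paternal effect (1.56%), 0.178% of long non-coding transcripts for the maternal effect (1.02%), 0.0755% of long non-coding transcripts for the paternal effect (1.00%) and 0.125% of microRNAs for the paternal effect (0.292%). Taken from MKI against WT alone, past 2-fold were 9.10% of mRNA genes for the maternal effect (1.77%) and 2.71% of long non-coding transcripts for the maternal effect (1.02%). Taken from PKI against WT alone they were 0.966% of mRNA genes for the paternal effect (1.56%) and 0.501% of microRNAs for the paternal effect (0.292%). The exact test on recovered reads, which compares libraries and not conditions, called at 2-fold or more 2.76% of microRNAs for PKI against WT (0.501%), 7.43% of microRNAs for MKI against WT (4.18%), 7.31% of microRNAs for HOMO against WT (4.05%) and 3.05% of microRNAs for HOMO against MKI (0.793%). Where a lower filter or a count test admits more features, or a pseudocount alters folds of low values, the construction itself moves the counts; for the other settings the cause was not tested.

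The share of higher values among features past 2-fold moved by over 10 percentage points as follows. For mRNA genes under quantile normalization it was 48.9% for PKI against WT (32.5%), 31.0% for MKI against WT (6.01%), 61.2% for HOMO against MKI (84.4%), 33.8% for MKI against PKI (13.4%), 20.9% for the maternal effect (9.73%), 76.5% for the paternal effect (89.2%) and 55.4% for the interaction (79.9%). For long non-coding transcripts under quantile normalization it was 54.2% for HOMO against WT (36.6%), 59.4% for HOMO against MKI (28.6%), 41.2% for MKI against PKI (59.2%), 59.5% for the paternal effect (37.7%) and 54.9% for the interaction (36.5%). For microRNAs under quantile normalization it was 59.3% for MKI against WT (13%), 51.8% for HOMO against WT (11.3%), 71.4% for HOMO against MKI (84.2%), 59.7% for MKI against PKI (8.33%), 52.1% for the maternal effect (4.44%) and 54.9% for the interaction (72.6%). For mRNA genes under TMM factors it was 67.6% for the interaction (79.9%). For long non-coding transcripts under TMM factors it was 33.5% for MKI against WT (51.0%), 49.5% for HOMO against WT (36.6%), 64.6% for HOMO against MKI (28.6%), 32.4% for MKI against PKI (59.2%), 64.7% for the paternal effect (37.7%) and 60.1% for the interaction (36.5%). For microRNAs under TMM factors it was 61.1% for HOMO against MKI (84.2%), 60.0% for the paternal effect (71.4%) and 52.9% for the interaction (72.6%).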

Other observations

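Of the tests in this part, that of a single left-over fraction was chosen only after the result was seen; the test of position was chosen before. Some further levels, chosen after their values were seen, were not printed so far. The long non-coding transcript with the highest value in WT, PKI and HOMO stood at 14818, 29660.3, 2.92 and 13466 FPKM in WT, PKI, MKI and HOMO. In MKI the highest value of any long non-coding transcript was 756 FPKM. The same transcript ranked first among those lower in MKI than WT. Column sums of that table were 45971, 66401, 15573 and 38677 FPKM in the same order of columns. Fabp7, a fatty acid binding protein gene of radial glia, was at 111, 123, 205 and 112 FPKM in the same order. The cardiac and placental transcription factor gene Hand1 was at 0.930, 1.02, 0.497 and 1.78 FPKM, the granulocyte gene S100a9 at 0.637, 0.721, 1.24 and 1.68 FPKM, and Ttr, encoding the thyroid hormone carrier transthyretin, at 29.6, 13.4, 24.6 and 33.4 FPKM.

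Domain microRNAs kept a median of 2.63% of their WT reads in MKI and 2.99% of their PKI reads in HOMO (50 microRNAs with at least 1000 WT reads). If the reads came from other libraries or from admixed wild-type tissue, each microRNA would keep about the same fraction, yet in MKI the fraction ran from 0.599% to 8.02%. The SD of the log2 ratio over microRNAs was 0.69 for MKI over WT and 0.67 for HOMO over PKI against 0.39 for PKI over WT, the smaller ratio of SDs being 1.70 (bootstrap 95% interval 1.27 to 2.06 over 10000 resamples, added after the ratio was seen), so carry-over is not excluded because the interval holds the bound of 1.5. Position along the domain may also play a part, since the fraction left went up with distance from the insertion in both independent pairs of columns (Spearman's rho 0.618 for MKI over WT, adjusted permutation p = 3e-05, the raw p of 1e-05 being the smallest that 100000 permutations can give; rho 0.317 for HOMO over PKI, adjusted permutation p = 0.0404; 49 precursors, 2-sided). For PKI over WT rho was 0.201 (adjusted permutation p = 0.166). The 3 relations were adjusted together, and precursors of a cluster are not independent. Across the 50 microRNAs the log2 ratios MKI over WT and HOMO over PKI were only weakly related (Pearson's r 0.235, Spearman's rho 0.157). The smaller rho with position in the 2 pairs lies under the bound of 0.4 set in advance, which keeps position and carry-over open.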
